A study of Mus musculus with 32 samples.

How the data were processed

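Gene expression was measured on 32 Agilent 44K mouse arrays with 2 colours, in laser-captured lumbar motor neurons and in the glia around them. Per the labels' protocols, female mice were killed with pentobarbital, frozen cords were sectioned at 12 µm and stained with cresyl violet, and cells were chosen by morphology with an anatomical atlas on a PixCell IIe instrument. About 500 cells were captured per mouse. RNA was purified with an RNeasy Micro kit, then amplified and labelled with a linear amplification kit for low RNA input. SOD1-G93A mice, which carry a mutant human superoxide dismutase, were 8 weeks old on a B6SJL background. TAU-P301L mice, which carry a mutant tau, were 16 weeks old on a B6D2F1 background, so model, age and strain differ together. Each array held a transgenic and a littermate control extract. There were 4 comparisons (motor neurons and glia of each model) with 4 littermate pairs each, and each pair was hybridised on 2 arrays with the dyes exchanged. A pair is therefore the unit of replication, with n = 4 per comparison, and the 2 arrays of a pair count once.

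The deposited scanner files hold spot intensity on a linear scale and a log10 ratio of Cy5 over Cy3. Per the file headers, the authors made these with Agilent Feature Extraction, with spatial detrending, background subtraction and a linear plus lowess dye normalization behind the processed signals. Version 8.5.1.1 is given by the submitters' processing notes for every array, and by the headers for the motor neuron arrays; the headers of the glia arrays give 9.5.1.1. Cell type and software version therefore cannot be told apart. The authors' deposited series matrix holds log10 ratios of transgenic over control, rounded to 1 decimal. Its columns followed the scanner log10 ratio of the same array, after turning the sign by dye, with absolute correlations of 0.982 to 0.999, absolute slopes of 0.998 to 1.00 and a median of 0 in each column. The matrix has 0 columns that were not matched to a sample.

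Mean spot intensity was corrected against the local background median with normexp and an offset of 50, in limma 3.58.1 under R 4.3.3. Log2 ratios were normalized within each array by loess, with control spots at weight 0, and spots carrying an outlier mark of the scanner software were left out while saturated spots were kept. Ratios were turned to transgenic over control from the dyes in the labels and averaged over the 2 arrays of a pair, so that dye effects cancel. A pair in which either array lacked a value was left missing. Of 43790 spots per array, 41534 were not controls and held 41174 probes. Probes were named through the reference gene table by accession (23374), by symbol (6733) or by synonym (2915), and 8152 had no name there and kept the name given in the file. A gene was read from its brightest probe, giving 27846 genes or single probes. It was tested in a comparison when well above background on both arrays in at least 4 of the 8 extracts.

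The 16 pairs entered a single limma fit with 1 mean per comparison, because 4 ratios alone leave 3 residual degrees of freedom. Each mean was tested against 0, and 4 differences of means were tested in the same fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. Control motor neurons were compared with control glia over 8 extracts each, from single-channel log2 intensity after loess and Aquantile normalization, with the colony as a covariate. A total of 28 gene lists (8 of cell type markers and 20 of functions) were tested in the 4 comparisons by the camera method on moderated statistics, with a preset inter-gene correlation of 0.01 and adjustment over the 112 tests. Each call is given again with a correlation estimated from the residuals, and by fry, which asks whether a list moves on balance in 1 direction. Correlations of effects between comparisons were tested by an exact two-sided enumeration that exchanges transgenic and control within pairs. Tests of list differences between comparisons were added after the data were seen.

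The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Sod1, Mapt and Prnp in every comparison, then up to 12 genes in each direction that passed the threshold with 1 sign in all 4 pairs. Where fewer than 10 genes passed, the 5 smallest p values in each direction were added as values that did not pass. These were taken only among genes with a symbol and 1 sign in all 4 pairs. It also named up to 4 members of each list that passed, or otherwise the 2 members with the smallest p, up to 5 members of each marker list between cell types and the 10 largest differences in each direction. Some genes that the rule selects are not reported here. Genes outside this rule are marked as chosen after their values were seen.

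Slide could not be used as a batch, since each slide held 1 array. The files gave 6 scan batches. Scans 1 and 2 each held 2 pairs of both motor neuron comparisons, scans 5 and 6 each held 1 pair of both glia comparisons, and scans 3 and 4 held 2 pairs of SOD1-G93A or of TAU-P301L glia. The alternatives were other signals, background corrections, normalizations, filters, weights and probes, unaveraged arrays, the 4 pairs of a comparison alone, scan and replicate blocks, and each pair left out in turn. Leaving out scan 5, using single motor neuron scans and using scan as a random block for lists were added after the data were seen.

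The gene tests were tested on simulated data with the spread of the real pairs, with 100 genes changed 1.5-fold and 100 changed 3-fold. Genes were drawn independently, with 1 spread per gene over all comparisons and the same pair value on both arrays. Recovery depends on the number and size of the planted changes, so the shares below are not the sensitivity in the real data. At 1.5-fold, 97% of changed genes were recovered among 13315 genes for SOD1-G93A motor neurons, 85% among 10475 for SOD1-G93A glia, 84% among 11672 for TAU-P301L motor neurons and 86% among 8923 for TAU-P301L glia. False calls numbered 13 of 209, 24 of 209, 13 of 197 and 16 of 202 in the same order. In the tests of differences at 1.5-fold, 71% and 70% were recovered for motor neurons minus glia in SOD1-G93A and TAU-P301L, and 70% and 64% for SOD1-G93A minus TAU-P301L in motor neurons and glia, with false calls of 18 of 186, 9 of 179, 22 of 191 and 15 of 178. Between control cell types 56% were recovered, with 13 false calls of 165. In the list test, 0 of 111 unshifted lists were called. Because the simulated genes were independent, this run says nothing about false calls of lists whose members move together. The share of probes well above background ranged from 35.2% to 77.6% in Cy3 and from 9.09% to 79.3% in Cy5, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.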

Results

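The series asked which genes differ between transgenic and littermate control mice in lumbar motor neurons and in the glia next to them, for SOD1-G93A, a model of amyotrophic lateral sclerosis, and TAU-P301L, a model of tauopathy. Each of the 4 comparisons held 4 littermate pairs measured on 2 arrays each. Values are mean log2 ratios of transgenic over control ± SD over the 4 pairs, unless stated otherwise. No pair of arrays held identical values. After normalization, the dye-swapped arrays of pairs 1 to 4 correlated at 0.55, 0.21, 0.0009 and 0.67 in SOD1-G93A motor neurons. In SOD1-G93A glia they correlated at -0.08, -0.46, 0.48 and 0.50. The values were 0.53, 0.34, -0.20 and 0.08 in TAU-P301L motor neurons and -0.74, 0.12, -0.09 and 0.44 in TAU-P301L glia. Low agreement was thus not confined to 1 scan or comparison.

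Control motor neuron captures carried more neuronal RNA than control glia captures. Neurofilament medium chain Nefm was higher in motor neurons by 1.59 ± 0.20 (SE, 8 extracts per cell type, limma adjusted p = 9.78e-05). The peptide gene Calca was higher by 2.23 ± 0.40 and the synaptic gene Snap25 by 2.24 ± 0.25. Of 19 motor neuron markers tested, 9 were higher in motor neurons and 2 in glia, among them Mnx1 at -0.36. Interneuron markers were also higher in motor neuron captures, with 8 of 16 passing, such as the enkephalin gene Penk at 1.04 and the glycine transporter gene Slc6a5 at 0.70. In glia, 7 of 16 astrocyte markers and 7 of 16 oligodendrocyte markers were higher and 0 lower, with glutamine synthetase Glul at -1.61, Mlc1 at -1.39 and myelin-associated Mag at -1.74. Other tested probes of Mag and Mobp had the opposite sign, and of the 2 other tested probes of Mbp only 1 had the same sign. Microglia markers went both ways, with 3 of 14 higher in glia and 1 in motor neurons, as did endothelial and pericyte markers, with 4 of 12 and 2, and red cell markers, with 1 of 3 each. Of 6 oligodendrocyte precursor markers, 1 was higher in glia. Adjusted over the list alone, 10 motor neuron markers were higher in motor neurons and 3 in glia, 9 interneuron markers in motor neurons and 1 in glia, and 7 astrocyte and 7 oligodendrocyte markers in glia and 0 in motor neurons. In the same way 0 oligodendrocyte precursor markers passed, and microglia markers had 1 higher in motor neurons and 2 in glia, endothelial and pericyte markers 3 and 4, and red cell markers 1 and 2.

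Over all 13063 genes tested, 5251 differed, 3526 higher in motor neurons and 1725 in glia. The largest differences toward motor neurons included the sodium pump subunit gene Atp1b1 at 2.02, Tspan13 at 1.97 and the pyruvate kinase gene Pkm at 1.65. Those toward glia included Rgs3 at -2.31, Sparc at -2.31, Gstm1 at -2.09 and Selenop at -2.08. Another probe of Sparc had the opposite sign. Cell type coincided with scan batch and software version, so these differences include any effect of both.

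**Figure D1:**
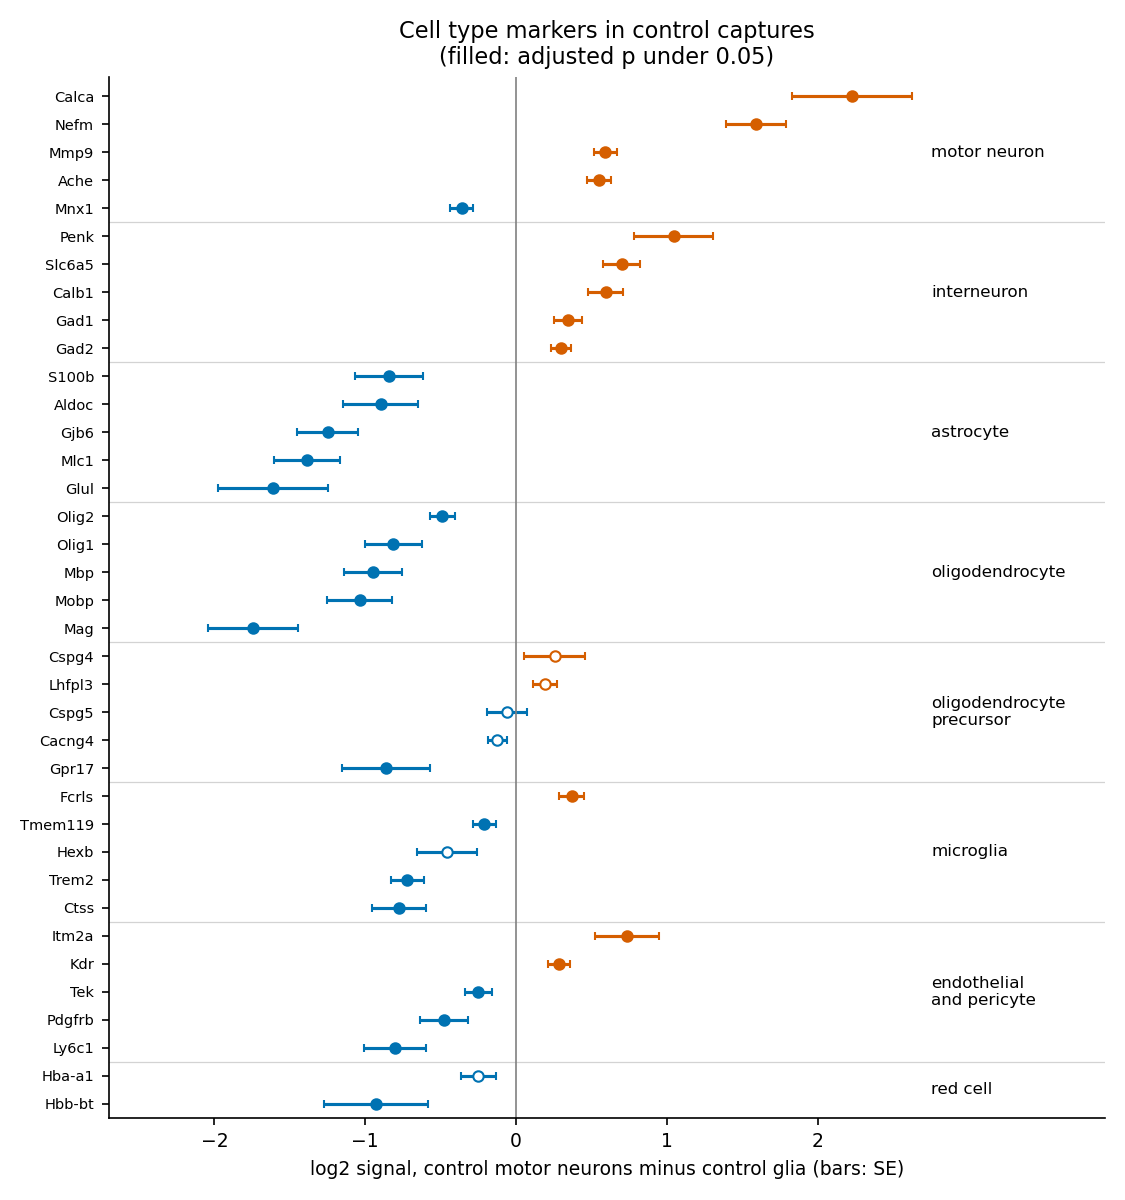
Log2 signal of control motor neurons minus control glia (x axis, bars are the SE, 8 extracts per cell type) for up to 5 markers per cell type (rows), with filled points for limma adjusted p under 0.05. Nefm (1.59) and Calca (2.23) lie to the right, and Glul (-1.61) and Mag (-1.74) to the left.

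Prnp, the prion protein gene, had the largest ratios of the 3 transgene-related genes. It lay above 0 in all 4 pairs of TAU-P301L motor neurons (1.08 ± 0.29, limma adjusted p = 0.245) and of TAU-P301L glia (0.88 ± 0.20, adjusted p = 0.132), and passed the threshold in neither. In SOD1-G93A motor neurons and glia it was -0.29 ± 0.33 and -0.14 ± 0.58, the latter turning positive under 2 of 17 alternatives. The Sod1 probe read -0.07 ± 0.17 in SOD1-G93A motor neurons and -0.10 ± 0.31 in SOD1-G93A glia, with a change of sign under 1 of 18 and 3 of 17 alternatives. The other 2 Sod1 probes were not well above background in those extracts. Mapt, the tau gene, read -0.10 ± 0.35 in TAU-P301L motor neurons, with a change of sign under 3 of 18 alternatives, and 0.08 ± 0.75 in TAU-P301L glia, with a change of sign under 2 of 17. Its other probes read 0.18 ± 0.16 and -0.17 ± 0.33 in TAU-P301L motor neurons, and 0.09 ± 0.04 and -0.03 ± 0.16 in TAU-P301L glia. In SOD1-G93A glia Mapt was 0.73 ± 0.19 (adjusted p = 0.0972), and its other probes read 0.15 and 0.55. The files do not say whether any of these mouse probes reads the transgene RNA.

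**Figure D2:**
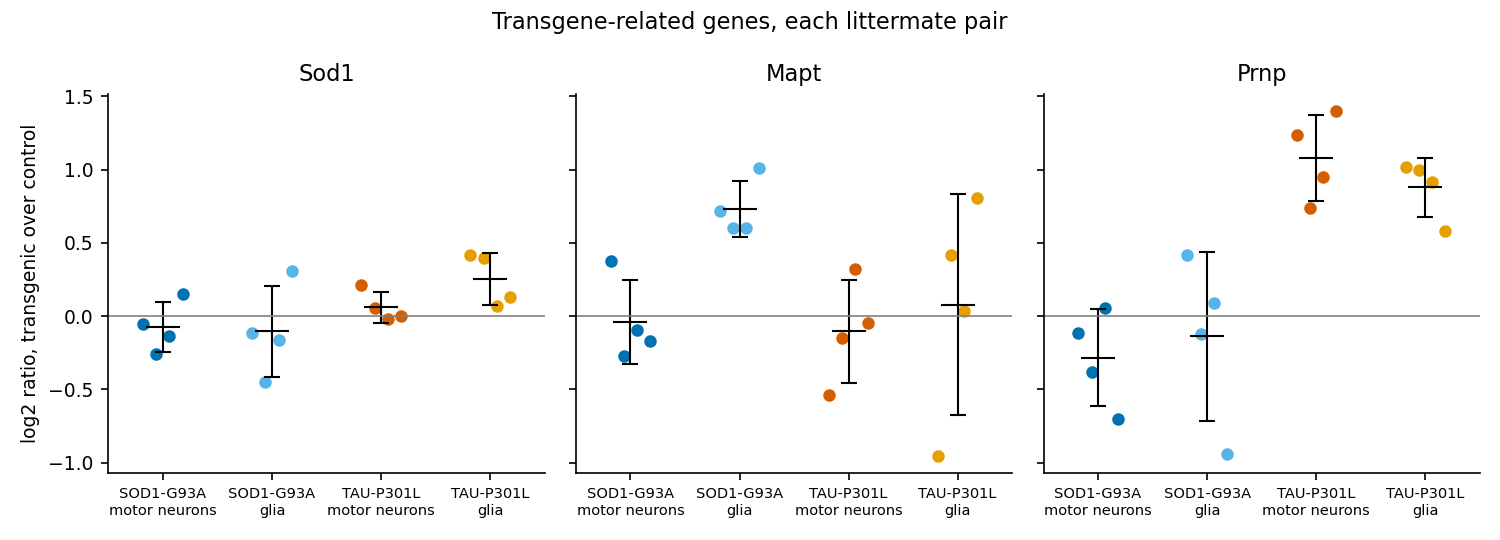
Log2 ratio of transgenic over control (y axis) for Sod1, Mapt and Prnp in each of the 4 pairs of each comparison (points), with the mean and SD in black. Prnp means are 1.08 and 0.88 in TAU-P301L motor neurons and glia, against -0.29 and -0.14 in the SOD1-G93A comparisons.

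In SOD1-G93A motor neurons at 8 weeks, proteasome genes were lower as a group, and a single gene passed the threshold. Of 34 proteasome genes tested, which encode the main protein-degrading complex, 30 lay below 0, with a list median of -0.17 and a mean of -0.14 (camera adjusted p = 3.88e-05, adjusted p = 0.208 with an estimated correlation and adjusted p = 0.0708 by fry). Adjusted over the list alone, 2 members passed, Psmb1 at -0.34 ± 0.22 and Psmd11 at -0.18 ± 0.05, and 0 passed over all genes. The list mean was -0.15 in scan 1 and -0.14 in scan 2. In the same pairs, ratios fell against the motor neuron minus glia difference in all 4 pairs, with slopes of -0.25 to -0.01, motor neuron markers had a mean of -0.10 and oligodendrocyte markers of 0.11, neither called. Sel1l3 fell by 0.23 ± 0.05 (limma adjusted p = 0.0204), with 1 sign in all 4 pairs, which the naming rule required. It was the only call among 13315 genes, of which 1398 had an unadjusted p under 0.05, against 666 for 5% of the genes tested. Among genes with a symbol and 1 sign in all 4 pairs, the smallest p values that did not pass were of Anxa2 at -0.44, Fhod3 at -0.36 and C9orf72 at -0.32. In the higher direction they were of Map1b, which encodes a microtubule-associated protein, at 0.98 ± 0.73, Pdlim5 at 0.23, Olfr774 at 0.16, Ankrd45 at 0.49 and Ybx2 at 0.38. The neuronal intermediate filament gene Prph, a member of the motor neuron, cytoskeleton and disease gene lists, was -0.23 ± 0.11 in the same direction in all 4 pairs (adjusted p = 0.217). Among 22 cholesterol synthesis genes, 3 passed when adjusted over the list alone, with Mvd at -0.18, and 0 over all genes. Among 48 cytoskeleton and axonal transport genes, 2 passed when adjusted over the list alone and 0 over all genes. The Sel1l3 call was lost without pair 1, 2 or 3 (adjusted p = 0.159, 0.0632 and 0.0694), and without pair 4 the count was 5. It stood with scan as a random block (1 gene), and 0 genes passed in scan 1 alone or scan 2 alone.

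In SOD1-G93A glia, 10 of 10475 genes passed, 7 higher and 3 lower, and 9 of them carry a gene symbol. Higher were Ank3 (0.63 ± 0.27), which encodes the ankyrin scaffold of axon initial segments and nodes, Ammecr1l (0.50 ± 0.15), the kinase gene Taok1 (0.41 ± 0.15), the Integrator subunit gene Ints3 (0.39 ± 0.09), the taurine transporter gene Slc6a6 (0.37 ± 0.17) and Ppargc1a (0.29 ± 0.09), a coactivator of genes for mitochondria. Lower were Akr1cl (-0.35 ± 0.14), the mucin gene Muc6 (-0.30 ± 0.11) and the nuclear pore gene Nup54 (-0.21 ± 0.05). Each of the 9 had the same sign in all 4 pairs, which the naming rule required, with limma adjusted p from 0.0408 to 0.0485. In total, 1696 genes had an unadjusted p under 0.05, against 524 for 5% of the genes tested. None of the 28 lists was called by camera (lowest adjusted p = 0.152), among which 11 of 12 endothelial and pericyte markers lay above 0 with a mean of 0.20 ± 0.22. Adjusted over the list alone 1 of them passed, the vascular receptor gene Flt1 at 0.77, and over all genes 0. Microglia markers had a mean of 0.06 with Trem2 at 0.19, and oligodendrocyte markers of 0.06 with Fa2h, a myelin lipid enzyme gene, at 0.24, each the 1 member of its list that passed when adjusted over the list alone. Ratios rose with the motor neuron minus glia difference in all 4 pairs, with slopes of 0.05 to 0.24. None of the 9 passed without pair 1 (adjusted p = 0.0545 each), 2 or 4, and Ank3, Slc6a6, Akr1cl and Nup54 did without pair 3. The count was 4 without pair 1, 0 without pair 2 and 0 without pair 4, 13 without pair 3, 12 with scan as a random block, and 0 without the scan 5 pairs, in a run added after the data were seen. Scan 5 held pair 2, whose 2 dye-swapped arrays correlated at -0.46 after normalization.

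In TAU-P301L motor neurons at 16 weeks, the list of 3 red cell markers was lower through its haemoglobin genes. Proteasome genes were higher as a group, and no single gene passed. Of 3 red cell markers, the haemoglobin genes Hbb-bt at -1.26 ± 0.81 and Hba-a1 at -0.31 ± 0.18 lay below 0 in all 4 pairs (list mean -0.52, camera adjusted p = 0.0347, adjusted p = 0.352 with an estimated correlation and adjusted p = 0.398 by fry). Adjusted over the list alone, 2 passed, and 0 over all genes. The list mean was -0.36 in scan 1 and -0.67 in scan 2. Of 34 proteasome genes, 24 lay above 0, with a median of 0.05 (camera adjusted p = 0.0258, adjusted p = 0.439 with an estimated correlation and adjusted p = 0.740 by fry), and Psmd3 at 0.32 and Psmb5 at 0.22 had the smallest p. Adjusted over the list alone 0 passed, and the list mean was 0.01 in scan 1 and 0.11 in scan 2. In the same pairs and scans, oligodendrocyte markers had a mean of 0.31 and -0.37, astrocyte markers of 0.15 and -0.19 and motor neuron markers of 0.09 and 0.14, none called, and slopes on the motor neuron minus glia difference ran from -0.04 to 0.13. The limma test called 0 of 11672 genes, and 494 had an unadjusted p under 0.05, fewer than the 584 that make 5% of the genes tested. Among genes with a symbol and 1 sign in all 4 pairs, the smallest p values in the higher direction were of Prnp, the mitochondrial ribosome gene Dap3 at 0.54 ± 0.22, Snrnp25 at 0.50, Rspo2 at 0.56 and Golt1b at 0.19. In the lower direction they were of the chemokine genes Ccl27a at -0.40 ± 0.20 and Ccl19 at -1.38 ± 0.41, the galactose enzyme gene Galt at -0.48 ± 0.20, Tmem234 at -0.30 and the initiator caspase gene Casp9 at -0.44. Ccl27a, Ccl19 and Galt are neighbours on chromosome 4, and in TAU-P301L glia they read -0.10, -1.05 and -0.21. Their neighbours Rpp25l at -0.44 and Dctn3 at -0.76 in motor neurons were chosen after their values were seen. Casp9 was the 1 of 23 apoptosis genes that passed when adjusted over the list alone. The proteasome call was lost without pair 1 or 2 (adjusted p = 0.171 and 0.187) and the red cell call without pair 2 or 3 (0.219 and 0.0888). Over all 23 alternatives for lists, the proteasome call was lost under 5 and the red cell call under 7. Without pair 3 the gene count was 14, and 0 genes passed with scan as a random block or in scan 1 or scan 2 alone.

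**Figure D3:**
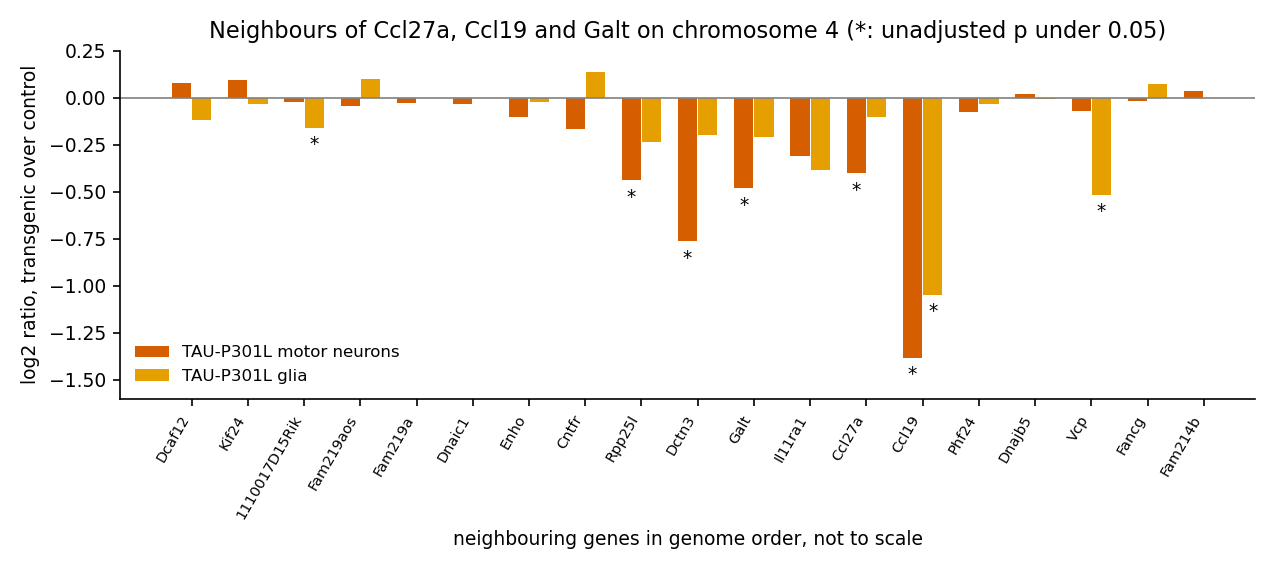
Log2 ratio of transgenic over control (bars, y axis) in TAU-P301L motor neurons and glia for genes around Ccl27a, Ccl19 and Galt on chromosome 4, in genome order and chosen after their values were seen, with stars for an unadjusted limma p under 0.05 and no bar where a gene was not tested. Ccl19 is lowest in both, at -1.38 and -1.05.

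In TAU-P301L glia, genes of oxidative phosphorylation and of the proteasome were higher as groups. Of 58 oxidative phosphorylation genes, 53 lay above 0, with a median of 0.15 and pair means of 0.16, 0.17, 0.12 and 0.16 (camera adjusted p = 2.48e-06, adjusted p = 0.00316 with an estimated correlation and adjusted p = 0.0708 by fry). Ndufc2 at 0.35 ± 0.16 and Ndufa4 at 0.31 ± 0.13 had the smallest p, and 0 members passed when adjusted over the list alone or over all genes. Of 29 proteasome genes, 24 lay above 0, with a median of 0.15 (camera adjusted p = 5.81e-04, adjusted p = 0.208 with an estimated correlation and adjusted p = 0.102 by fry). Adjusted over the list alone 1 passed, Psmb4 at 0.55 ± 0.43, and over all genes 0. Uchl1, a deubiquitinase abundant in neurons, was 0.90 ± 0.31. In the same pairs, ratios rose with the motor neuron minus glia difference in all 4 pairs, with slopes of 0.12 to 0.19. Astrocyte markers had a mean of -0.18 ± 0.09, with the transporter gene Slc1a2 at -0.56 and Clu at -0.38, and oligodendrocyte markers of -0.13 ± 0.13, with Olig2 at -0.21 and Sox10 at -0.29, neither called (adjusted p = 0.0833 and 0.212). The astrocyte list passed under 5 of 23 alternatives. The 2 red cell markers tested there had a mean of -0.46 ± 0.23, below 0 in all 4 pairs and not called (camera adjusted p = 0.159). The limma test called 0 of 8923 genes, and 1227 had an unadjusted p under 0.05, against 446 for 5% of the genes tested. Among genes with a symbol and 1 sign in all 4 pairs, the smallest p values in the higher direction were of Foxo6 at 0.47, Ccdc28a at 0.56, Dap3 at 0.59 ± 0.22, Pigp at 0.36 and Gsdme at 0.42. In the lower direction they were of Ppfia1 at -0.45, Muc6 at -0.29, C6 at -0.17, Apln at -0.28 and Gtf2h2 at -0.27. Muc6 changed sign under 1 of 17 alternatives. The gene count was 1 without pair 1 and 1 without pair 3, 0 with scan as a random block, and 2 without the scan 5 pairs, added after the data were seen; in scan 5 the dye-swapped arrays of pair 1 correlated at -0.74.

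**Figure D4:**
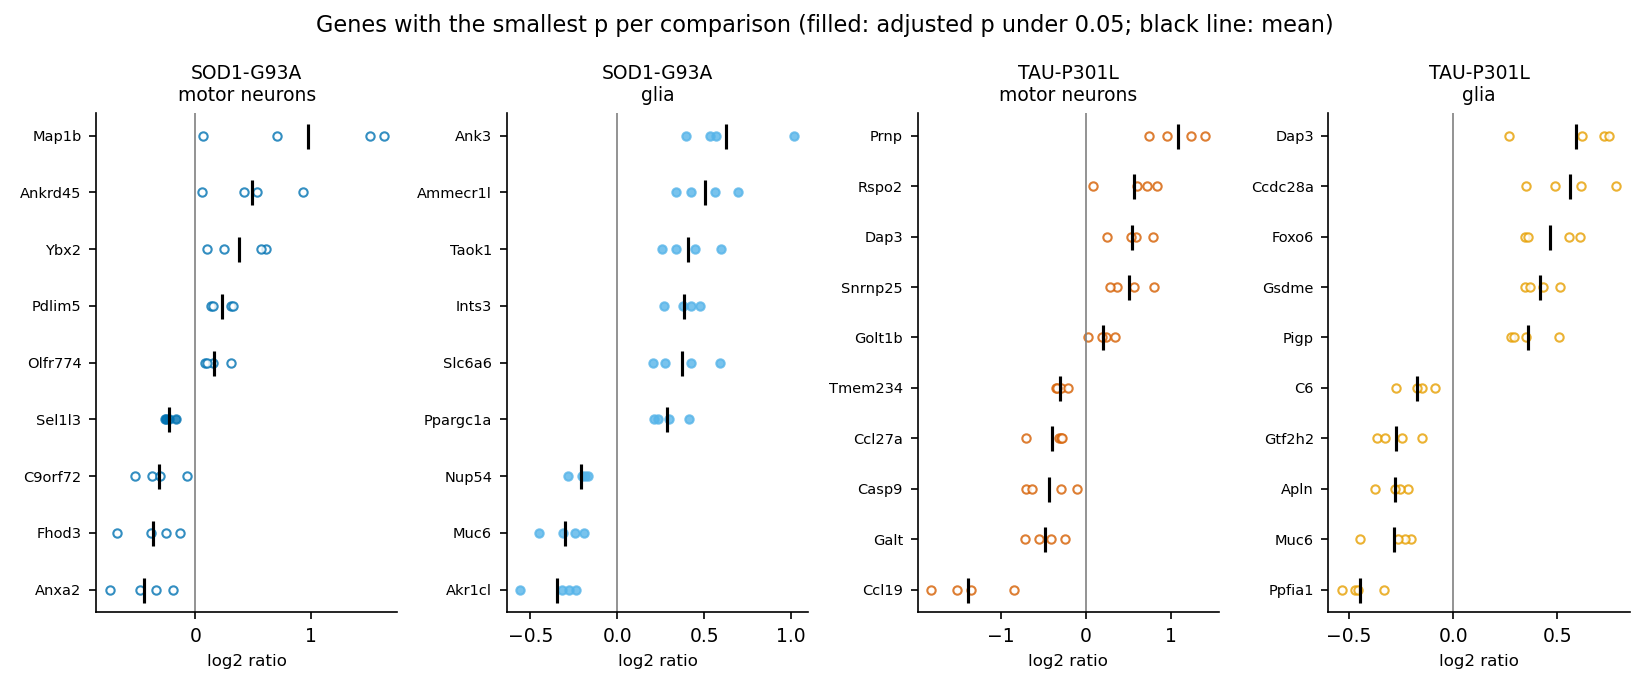
Log2 ratio of transgenic over control (x axis) in each pair (points) and its mean (black line) for the genes named by smallest p or by passing the threshold in each comparison, with filled points for limma adjusted p under 0.05. Filled points are Sel1l3 (-0.23) in SOD1-G93A motor neurons and 9 genes in SOD1-G93A glia.

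**Figure D5:**
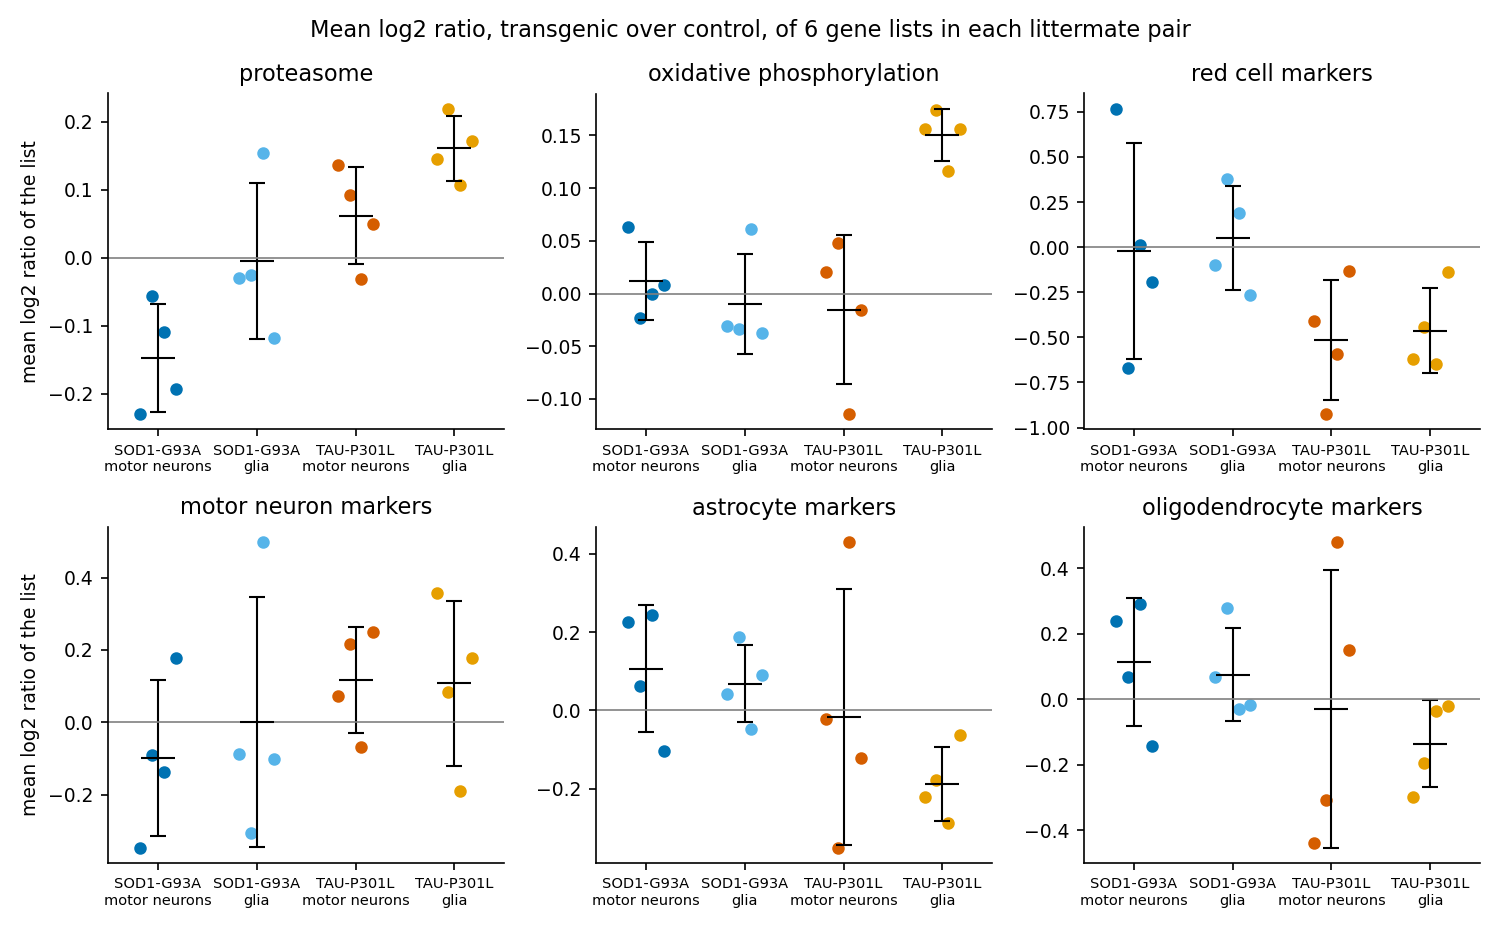
Mean log2 ratio of transgenic over control (y axis) of 6 gene lists in each of the 4 pairs of each comparison (points), with the mean and SD over pairs in black. Oxidative phosphorylation lies above 0 in all 4 pairs of TAU-P301L glia, between 0.12 and 0.17.

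Effects were then compared between cell types and between models. No gene passed the test of a difference between motor neurons and glia of either model, or between models in either cell type. The limma test called 0 genes in each of the 4, and 1806, 618, 1375 and 682 genes had an unadjusted p under 0.05 for motor neurons minus glia in SOD1-G93A, the same in TAU-P301L, and SOD1-G93A minus TAU-P301L in motor neurons and in glia. In the same order, 5% of the genes tested is 700, 609, 682 and 548. Genes are not independent, so an excess over these counts is not a test. Without SOD1-G93A motor neuron pair 2 or TAU-P301L motor neuron pair 3, the count for models in motor neurons was 4 or 1. Leaving out SOD1-G93A glia pair 4 gave 1 for SOD1-G93A cell types, TAU-P301L glia pair 1 gave 1 for TAU-P301L cell types and TAU-P301L glia pair 2 gave 1 for models in glia. With scan as a fixed block, 0 genes passed for models in both cell types. In glia that fit rests on scan 5 and scan 6, with 1 pair of each model in each, since the other glia scans held 1 model only. Prnp differed between models by -1.37 in motor neurons (adjusted p = 0.184) and -1.02 in glia (adjusted p = 0.448), and 0 genes passed the threshold in 2 or more comparisons.

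Across genes, which are not independent replicates, effects in SOD1-G93A motor neurons ran opposite to those in TAU-P301L motor neurons (10990 genes, r = -0.38, exact p = 0.0625, rho = -0.38, exact p = 0.0312) and in TAU-P301L glia (6980 genes, r = -0.41, exact p = 0.0469, rho = -0.37, exact p = 0.0469). None of the 6 relations passed after adjustment, and these had an adjusted p of 0.188 each for r and 0.141 each for rho, where the smallest exact p allowed is 0.0156. Pairs of the same comparison agreed little with each other over 7986 genes. Their median r was 0.03 (-0.18 to 0.10) in SOD1-G93A motor neurons and -0.04 (-0.30 to 0.37) in TAU-P301L motor neurons. In glia it was 0.16 (0.11 to 0.50) for SOD1-G93A and 0.22 (-0.06 to 0.50) for TAU-P301L. Within scan 1 and within scan 2 the motor neuron correlation was -0.28 and -0.23, with 2 pairs of each model, and between scans it was -0.19 (SOD1-G93A in scan 1) and -0.08 (SOD1-G93A in scan 2). The glia of both models correlated at r = 0.39 (exact p = 0.156, rho = 0.31), motor neurons and glia of TAU-P301L at 0.34 (exact p = 0.109, rho = 0.28), those of SOD1-G93A at -0.11 (exact p = 0.688, rho = -0.03), and SOD1-G93A glia with TAU-P301L motor neurons at -0.01 (exact p = 0.922, rho = -0.04). Their adjusted p for r were 0.234, 0.219, 0.825 and 0.922. With 1 pair of each model per scan, the glia correlation was -0.20 in scan 5 and 0.08 in scan 6, and between these scans -0.12 (SOD1-G93A in scan 5) and -0.03 (SOD1-G93A in scan 6).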

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

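The tests of prion gene sequence in transgene RNA, of a single transcript read by several probes, of list differences between comparisons, and of the capture share for SOD1-G93A motor neurons with TAU-P301L glia and for the lists of TAU-P301L motor neurons were chosen after the results were seen. Of 71 sets of 4 pair values searched for a stray value by Dixon's test, 3 held one, and chance gives about 1 in 20. Ccl27a in TAU-P301L motor neurons was -0.71 in pair 1, away from the other pairs. The share of genes without a value was 12.3% in pair 2 of SOD1-G93A glia and 15.5% in pair 1 of TAU-P301L glia, the pairs of scan 5.

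Tests of the difference between comparisons by camera passed for 11 lists, of which 2 passed with an estimated correlation. Values are medians of the members' differences in log2 ratio. The proteasome differed by -0.17 for SOD1-G93A motor neurons minus glia (adjusted p = 0.0472, and adjusted p = 0.660 with an estimated correlation). Oxidative phosphorylation differed by -0.14 for TAU-P301L motor neurons minus glia (adjusted p = 0.0272 with an estimated correlation). No scan held both cell types, so cell type and scan cannot be told apart here.

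For SOD1-G93A minus TAU-P301L in motor neurons, the proteasome differed by -0.21 (adjusted p = 0.0987 with an estimated correlation), motor neuron markers by -0.23 and cytoskeleton and axonal transport by -0.10 (adjusted p = 0.773 each with an estimated correlation) and cholesterol synthesis by -0.058 (0.411). With scan as a fixed block these 4 passed, with adjusted p of 5.45e-06, 0.0267, 0.0255 and 0.0257, and none did with an estimated correlation (adjusted p = 0.0811, 0.681, 0.543 and 0.25). Mean differences within scan 1 and scan 2 were -0.16 and -0.26 for the proteasome, -0.07 and -0.36 for motor neuron markers, -0.15 and -0.12 for the cytoskeleton list and -0.19 and -0.13 for cholesterol synthesis. Of markers of other cells, none called, oligodendrocyte (-0.24 and 0.53), astrocyte (-0.08 and 0.33), endothelial and pericyte (-0.20 and 0.32) and interneuron markers (-0.02 and 0.22) changed sign between the scans, and oligodendrocyte precursor (0.58 and 0.18), microglia (0.02 and 0.18) and red cell markers (0.27 and 0.72) did not.

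For the same difference in glia, oxidative phosphorylation differed by -0.18 (adjusted p = 0.00141 with an estimated correlation) and the proteasome by -0.19 (0.0987). Astrocyte markers differed by 0.22, oligodendrocyte markers by 0.21 and microglia markers by 0.11 (adjusted p = 0.773 each with an estimated correlation). With scan as a fixed block, the glia difference between models rests on scan 5 and scan 6, since the other glia scans each held 1 model only. The fit is therefore not a check over all glia pairs. In scan 5 the dye-swapped arrays correlated at -0.46 for the SOD1-G93A pair and -0.74 for the TAU-P301L pair. In that fit, astrocyte and microglia markers no longer passed (adjusted p = 0.18 and 0.148) and the other 3 did. Motor neuron markers newly passed at -0.31 (adjusted p = 0.0154, and adjusted p = 0.628 with an estimated correlation). With an estimated correlation in that fit, oxidative phosphorylation passed (adjusted p = 0.00496), and oligodendrocyte markers and the proteasome did not (0.681 and 0.235). Mean differences within scan 5 and scan 6, with 1 pair of each model, were -0.19 and -0.20 for oxidative phosphorylation, -0.17 and -0.25 for the proteasome, 0.41 and 0.22 for astrocyte, 0.58 and 0.26 for oligodendrocyte 0.23 and 0.11 for microglia and -0.66 and -0.17 for motor neuron markers.

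Prnp lay above 0 in all pairs of both TAU-P301L comparisons, without passing the threshold over all genes. A dye or array artefact is argued against, since Prnp lay above 0 on 16 of the 16 TAU-P301L arrays, in both dye orientations. A strain segment around Prnp that differs between littermates cannot be told apart, because 20% of 55 tested neighbours within 5 Mb had an unadjusted p under 0.05 in either comparison (exact binomial 95% interval 10.4% to 33.0%), against 17.0% of 7440 genes. Transgene RNA that carries prion gene sequence cannot be told apart either, because 8 of 8 TAU-P301L pairs lay above the highest SOD1-G93A pair of the same cell type, which any source of higher Prnp in these mice would give. Age and strain differ between the models together with the transgene and stay open, untested.

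Effects in SOD1-G93A motor neurons ran opposite to those in TAU-P301L motor neurons and glia across genes, without passing after adjustment, and the 5 called lists were weighed with them. A different share of motor neuron RNA in transgenic and control captures was tested by taking out each pair's slope on the motor neuron minus glia difference. The correlation between motor neurons kept 86.0% of its size (-0.38 before, -0.33 after). Oxidative phosphorylation in TAU-P301L glia kept 94.0% of its mean shift (camera adjusted p = 1.44e-06 after). These values argue against a linear share along this axis as the whole cause of either. Error in the axis, which also coincides with scan batch and software version, would leave part of such a share in place. A different capture share is therefore not excluded. It cannot be told apart for the correlation with TAU-P301L glia (55.2% kept, -0.41 and -0.22), the proteasome in SOD1-G93A motor neurons (61.7% kept, mean -0.14 and -0.09) and the proteasome in TAU-P301L glia (72.2% kept, 0.16 and 0.12), which lie between the bounds set, nor for TAU-P301L motor neurons, where both calls ended: red cell markers kept 97.1% (-0.52 ± 0.33 and -0.50 ± 0.33, SD over pairs) as the adjusted p moved from 0.0347 to 0.0525, and the proteasome kept 75.2% (0.065 ± 0.071 and 0.049 ± 0.064) with a smaller mean and an adjusted p of 0.0807. More RNA in 1 arm of the arrays was weighed by counting pairs. In detected probes, 3 of 8 motor neuron pairs differed in the direction first named and 5 in the opposite one. An imbalance shared by all pairs needs all 8 in 1 direction and is argued against for the correlation between motor neurons. An imbalance in some pairs is not, because the correlation rests on means over pairs and the count ignores size. In SOD1-G93A motor neuron pair 4, 14.7% of probes were well above background in the transgenic extract and 23.9% in the control extract. Differences of transgene, age and strain stay open, untested.

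The neighbouring genes Ccl27a, Ccl19 and Galt lay below 0 in all 4 pairs of TAU-P301L motor neurons, which the naming rule required, without passing the threshold over all genes. 1 transcript read by several probes cannot be told apart, because the 3 different orders of the 4 pairs among the genes rest on pair 1, which is the lowest pair for Ccl27a (-0.71) and Ccl19 (-1.82) and the highest for Galt (-0.25), and on near ties of Ccl27a in the other pairs (-0.32, -0.30 and -0.28). A strain segment or copy number difference between littermates cannot be told apart from other causes. Each of the genes lay below 0 in at least 3 of the 4 pairs of TAU-P301L glia, which any cause shared by both cell types would give. Their means in glia were -0.10, -1.05 and -0.21, against -0.40, -1.38 and -0.48 in motor neurons. An effect of the transgene on these genes was not tested.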

How the results depend on the processing

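The runs without the scan 5 pairs, in single scans and with scan as a random block for lists were chosen after the data were seen. No value past its threshold changed sign, but sizes depended on the setting. Over all alternatives, Sel1l3 in SOD1-G93A motor neurons ranged from -0.75 to -0.17. In SOD1-G93A glia, Ank3 ranged from 0.50 to 0.84, Taok1 from 0.32 to 1.16 and Nup54 from -0.60 to -0.14. Of 5814 gene values under other settings, 5292 kept their direction and side of the threshold or moved by less than 1 SD, 183 no longer passed, 89 newly passed and 250 moved by more. Of 2576 list values, 2413 did the same. The count of genes different between control motor neurons and control glia (5251) ranged from 3989 to 7461. For the values below, the cause was not tested. For SOD1-G93A motor neurons (1 gene), the count was 0 with Agilent's processed signals, the series matrix, detection in all 8 extracts, array weights, its 4 pairs alone, scan 1 alone and scan 2 alone, 42 without background correction, 3 with scale normalization and 6 with arrays unaveraged. For SOD1-G93A glia (10 genes), it was 0 with processed signals, no background correction, median centring, scale normalization, the series matrix, no filter, its 4 pairs alone and without the scan 5 pairs, 4 with detection in all 8 extracts, 194 with array weights and 159 unaveraged. For TAU-P301L motor neurons (0), it was 1 with array weights and 7 unaveraged. For TAU-P301L glia (0), it was 5 with detection in all 8 extracts, 895 with array weights, 25 unaveraged and 2 without the scan 5 pairs. Differences (0 each) gave 1 for SOD1-G93A cell types, 19 for models in motor neurons and 29 for models in glia unaveraged, and 1 for TAU-P301L cell types without the scan 5 pairs. Lists (5 called) gave 1 with an estimated correlation, 0 by fry and 8 with no filter. The correlation of SOD1-G93A glia with TAU-P301L motor neurons (-0.01) was 0.025 with processed signals, 0.014 without background correction, 0.0058 with detection in all 8 extracts and 0.031 without the scan 5 pairs.

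Leaving out 1 pair gave 0 to 5 genes for SOD1-G93A motor neurons, 0 to 13 for SOD1-G93A glia, 0 to 14 for TAU-P301L motor neurons and 0 to 1 for TAU-P301L glia. It gave 0 to 1 for both cell type differences and for models in glia, and 0 to 4 for models in motor neurons. List calls ranged from 4 to 11, with 9 without SOD1-G93A motor neuron pair 4 and 11 without TAU-P301L motor neuron pair 3. The correlation of SOD1-G93A motor neurons with glia ranged from -0.21 to 0.099, positive without motor neuron pair 3 or glia pair 3. That of SOD1-G93A glia with TAU-P301L motor neurons ranged from -0.17 to 0.19, the highest without TAU-P301L motor neuron pair 1. SOD1-G93A motor neurons correlated at -0.44 to -0.24 with TAU-P301L motor neurons and at -0.43 to -0.22 with TAU-P301L glia. The range was 0.17 to 0.47 between the glia of both models and 0.16 to 0.40 between TAU-P301L motor neurons and glia.

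The labels do not say that samples with the same number share an animal. Deviations of same-numbered motor neuron and glia pairs correlated across genes at -0.13 to 0.26 in SOD1-G93A and 0.077 to 0.30 in TAU-P301L, and those of the models at -0.018 to 0.22 in motor neurons and -0.17 to 0.32 in glia. The own number correlated best in 1, 3, 0 and 1 of 4 samples. With the number as a replicate block, each difference called 0 genes, and genes different between control motor neurons and control glia numbered 4986. Signal over background limits detection, with as few as 9.09% of probes well above it in Cy5.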

Other observations

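The exchanges and splits of samples reported here were planned. In SOD1-G93A motor neurons, 17 of 28 ion channel and pump genes lay above 0 (camera adjusted p = 0.152). With the slope on the motor neuron minus glia difference taken out, the mean of this list went from 0.11 to 0.17 and it was called (adjusted p = 0.0313, and adjusted p = 0.104 with an estimated correlation). Among its members the potassium channel gene Kcnc1 was 0.27 ± 0.26 (SD, 4 pairs), and in TAU-P301L motor neurons it was -0.32 ± 0.20, with 1 sign in all 4 pairs of each. In SOD1-G93A glia, the heat shock regulator gene Hsf1 was -0.68 ± 0.35, the angiogenin gene Ang -0.61 ± 0.35 and the activity-regulated gene Arc 0.24 ± 0.07, each with 1 sign in all 4 pairs and none past the threshold (limma adjusted p = 0.109, 0.101 and 0.106). In TAU-P301L glia, 17 of 23 heat shock and chaperone genes lay above 0 (camera adjusted p = 0.159), with the co-chaperone gene Dnajb1 at 0.47 ± 0.44 and above 0 in 3 of 4 pairs. The lipid carrier gene Apoe was -0.52 ± 0.23, the asparagine synthetase gene Asns 0.44 ± 0.10 and the ATPase gene Vcp -0.52 ± 0.10, each with 1 sign in all 4 pairs (limma adjusted p = 0.295, 0.245 and 0.181). Vcp lies among the neighbours of Ccl19 on chromosome 4, but was -0.07 in TAU-P301L motor neurons. The tested genes between them, Phf24 and Dnajb5, read -0.08 and 0.02 in motor neurons and -0.03 and -0.01 in glia.

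Exchanging transgenic and control within pairs gives 8 arrangements, too few for a share under 0.05, and where the real count is 0 all 8 reach it by construction. In SOD1-G93A motor neurons, 3 arrangements called as many genes (real 1, highest other 4) and 7 as many lists (real 1, highest other 4). In SOD1-G93A glia, 1 arrangement, the real one, called as many genes (real 10, highest other 1) and 8 as many lists (real 0, highest other 3). In TAU-P301L motor neurons, 8 called as many genes (real 0, highest other 37) and 6 as many lists (real 2, highest other 6). In TAU-P301L glia, 8 called as many genes (real 0, highest other 0) and 2 as many lists (real 2, highest other 2). The 37 genes came from exchanging pair 3 of TAU-P301L motor neurons, which points to a structure of these pairs that was not tested. In TAU-P301L motor neurons, the exchange that sets the pairs of scan 2 against those of scan 1 called 3 lists, more than the real 2, and the means of the real lists within scan 1 and scan 2 were -0.36 and -0.67 for red cell markers and 0.01 and 0.11 for the proteasome.

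Splits of 8 pairs into 4 and 4 number 35, and for each of the 4 differences all 35 called at least the real 0 genes by limma, which a real count of 0 gives by construction and which decides nothing about chance. The highest other counts were 54 for SOD1-G93A cell types, 1 for TAU-P301L cell types, 6 for models in motor neurons and 1 for models in glia. The 54 genes came from motor neuron pairs 1 and 4 with glia pairs 2 and 4 against the other pairs, which points to a structure of the samples that follows no scan and was not tested. The split of motor neuron pairs by scan called 0 genes, as did the real split with scan as a fixed block. For control motor neurons against control glia, 1 of 100 splits, the real one, gave as many genes (real 5251, highest other 3389). Chance is argued against but not excluded, since 1 of 100 is the smallest share that could be reached. The real split is also the split by scan batch and software version, so its rank does not separate cell type from these.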
